A study of Homo sapiens with 8 samples.

How the data were processed

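Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 697 cells, an established human pre-B leukaemia line. The series holds 8 libraries, 1 per antibody (AIOLOS, IKAROS, MTA2, Mi2, HDAC2, OCT2 and OCAB) and 1 input library of genomic DNA taken without an antibody. Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum. Nuclei were sonicated, adapters were ligated, the DNA was amplified over 15 PCR cycles, and fragments of about 250 bp, adapters included, were sequenced on an Illumina HiSeq 2500. The amplified reads carry no molecular identifier. Because each antibody had 1 library, every interval given here covers counting error only.

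The deposited data are 7 peak lists, 1 for each antibody; the input has no list of its own and enters through peak calling. Per the submitters' processing notes, the tools were CASAVA 1.8.2 (1.4 for HDAC2), Bowtie2 2.3.2.2 and HOMER 4.9.1, on build hg19. The lists have the columns of HOMER's findPeaks, and each list belongs to 1 library with no pooling recorded. Per the file headers, the HDAC2 list was made with a minimum of 4-fold over input and over the surrounding 10000 bp, a Poisson p-value limit of 0.0001 for both, and a false discovery rate of 0.001; of 28008 putative peaks, 8205 were removed against input and 3678 against the local signal. The parameters of the other 6 lists are not given in the sources used here. Their values show that they were not the same. The highest p-value over input was 9.5e-05 in the HDAC2 list, 8.32e-10 for IKAROS, 8.92e-10 for OCT2, and below 1e-10 in the other 4 lists.

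Peak height is the deposited signal column of tags in the peak per 10 M tags of the library, which the authors obtained from HOMER. The count of tags in a peak is deposited as whole numbers for 5 of the lists. For IKAROS and MTA2 the deposited signal is the tag number scaled to the depth of the input. The input signal in each peak is likewise the authors' value, scaled to the depth of the ChIP library for 5 lists and left unscaled for IKAROS and MTA2. The deposited fold columns are ratios of ChIP tags to input tags, to the surrounding region and to the tags that distinct positions would give. The deposited p-value columns are HOMER's Poisson p-values against input and against the surrounding region. The focus column the authors deposited is a fraction, the share of tags lying where a peak around its centre would put them. The score column the authors deposited is HOMER's own peak score. These per-peak values describe, rank or filter peaks within a list. Between lists, median folds are set side by side as description, heights are related by rank alone, and 1 p-value limit is applied to every list as an alternative.

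Depth was recovered as the median of peak tags over peak height among high peaks. It came to 22.8 M tags for MTA2, 18.5 for Mi2, 10.9 for HDAC2, 23.4 for IKAROS, 16.1 for AIOLOS, 17.6 for OCAB and 18.3 for OCT2. The HDAC2 header gives 10915066 tags. The input behind 6 of the lists held about 21.3 M tags, and the input behind HDAC2 19.99 M, so the input used for that list was not of the same size. HDAC2 was the shallowest library and had the loosest p-value limit, so its list length is not comparable with the others.

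Peaks of different lists were called shared where they overlapped by at least 1 bp. Chance overlap was taken from 1000 random placements of the shorter list, with the widths and chromosomes kept, within the span that peaks of all lists cover on each chromosome. Overlapping peaks of all lists were merged into regions. The odds ratio of each pair was computed over merged regions that hold a peak of at least 1 of the other 5 lists, with the 95% interval of Robins, Breslow and Greenland. Shares have Wilson 95% intervals, differences of shares have Newcombe intervals, and median ratios have intervals from 1000 bootstrap draws over peaks. Peaks and regions are not replicates. With 1 library per antibody there was no replicate check, so no p-value between proteins was computed. Overlap and odds ratio code was tested on simulated peaks; the largest deviation from the 7 simulated quantities was 3.53%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

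The comparisons, the alternatives and the rule for named regions were fixed before the data were examined. The rule takes, for each comparison, the 10 co-bound regions with the highest peak in the list of the protein named first (MTA2, IKAROS, MTA2, OCAB and OCAB), on chromosomes 1 to 22 and X, with at least 4-fold over input. Coordinates are those of the deposited lists, on hg19. The gene annotation at hand was on GRCh38, another build, so no peak was assigned to a gene. Intended results that need such an assignment or a genome sequence were not run: promoter shares, promoter and distal strata, gene list counts and motif shares. Odds ratios therefore have no promoter or distal stratum, and the genes that the rule named in any case are not reported here.

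The alternatives chosen beforehand were a fold over input of at least 2 times the lowest in each list, the 2000 highest peaks of each list, chromosomes 1 to 22 alone, overlap by 50 percent of the shorter peak, peak centres within 100 bp, and all merged regions as background. Added after the data were seen were 1 p-value limit of 1e-10 for every list, NuRD regions without HDAC2, strata by the number of other lists, a logistic model with the other 5 lists as terms, regions without IKAROS, AIOLOS and HDAC2, and backgrounds in which no region enters through the compared lists alone (for MTA2 in the OCAB and OCT2 classes, regions with Mi2, HDAC2, IKAROS or AIOLOS, and likewise for each other protein there; and regions with AIOLOS, OCAB or OCT2 for IKAROS by number of subunits). Counts of peaks in windows of 1 Mb and near chromosome ends were also added after the data were seen; windows with fewer than 10 peaks of a list were not ranked.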

Results

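Binding of 7 proteins was mapped by ChIP-seq in 697 cells, an established line of human pre-B leukaemia cells. MTA2, Mi2 and HDAC2 are subunits of NuRD, a complex that joins nucleosome remodelling to histone deacetylation. IKAROS and AIOLOS are related zinc-finger transcription factors of lymphocytes. OCT2 binds the octamer sequence, and OCAB is the B-cell coactivator that is recruited through octamer-binding factors. Each antibody had 1 library, and the series holds 1 input library; whether that input was the control for every list is not settled by the sources. The title of the series ties MTA2 and NuRD to B-cell development and asks how MTA2 works together with OCAB.

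IKAROS had the longest list, with 53948 peaks from 23.4 M tags, followed by AIOLOS with 38101 peaks from 16.1 M and MTA2 with 28760 peaks from 22.8 M. The HDAC2 list held 16125 peaks, the Mi2 list 10303, the OCT2 list 8129 and the OCAB list 4440. Peaks took up 18.9% of the tags in the IKAROS library and 14.2% in the AIOLOS library, against 6.02% for MTA2, 2.67% for HDAC2, 1.72% for Mi2, 1.5% for OCT2 and 1.06% for OCAB. The median peak stood 16.5-fold over input for AIOLOS and 15.2-fold for IKAROS, and 7.33-fold for HDAC2. At a common p-value limit of 1e-10 over input, the HDAC2 list fell to 6674 peaks, while IKAROS kept 51619 and OCT2 kept 7289. No antibody had a replicate library, so list lengths carry no error and cannot be set against the spread between libraries.

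The 159806 peaks merged into 74123 regions with a median width of 305 bp. Of these regions, 44.7% held a peak of 1 list alone, 23.4% held peaks of 2 lists, and 482 regions (0.65%) held peaks of all 7. The commonest kinds of region were IKAROS alone (16331 regions), IKAROS with AIOLOS (11304) and MTA2 with IKAROS and AIOLOS (7607). Every pair of lists shared more peaks than 1000 random placements gave. Random placement produced mean overlaps between 0.168% and 1.26% of the shorter list over the 21 pairs, against observed overlaps between 16.4% and 85.9%.

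**Figure D1:**
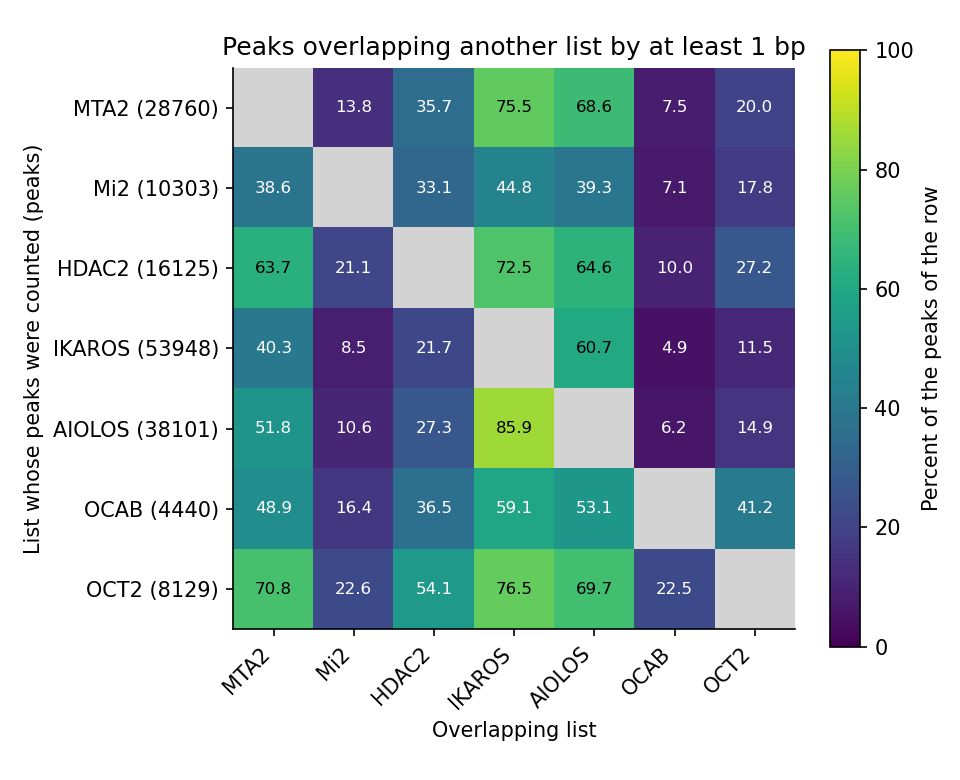
Percent of the peaks of each list (rows, with the number of peaks) that overlapped a peak of another list (columns) by at least 1 bp. The largest share was that of AIOLOS peaks at IKAROS peaks (85.9%), and 70.8% of OCT2 peaks and 48.9% of OCAB peaks overlapped MTA2.

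The first comparison asked how far the 3 NuRD subunits were found at the same places. MTA2, Mi2 and HDAC2 were found together in 2903 regions, which took in 28.2% of Mi2 peaks (95% Wilson interval 27.3 to 29.1), 18.0% of HDAC2 peaks (17.4 to 18.6) and 10.1% of MTA2 peaks (9.79 to 10.5). HDAC2 lay with MTA2 much more often than Mi2 did: 63.7% of HDAC2 peaks (62.9 to 64.4) and 38.6% of Mi2 peaks (37.7 to 39.6) overlapped an MTA2 peak. Mi2 overlapped HDAC2 at 33.1% of its peaks (32.2 to 34.0). A large part of the Mi2 list stood apart, with 4402 of the merged regions holding Mi2 and no other protein, while 4233 held MTA2 alone and 2473 held HDAC2 alone.

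Among MTA2 peaks, 2526 overlapped both a Mi2 and an HDAC2 peak, while random placement of those lists gave a mean of 0.313 and at most 3. Over regions bound by at least 1 of the other 5 proteins, the odds ratio was 9.87 for HDAC2 with MTA2 (95% interval 9.43 to 10.3), 6.98 for Mi2 with HDAC2 (6.6 to 7.4) and 5.05 for Mi2 with MTA2 (4.76 to 5.36). Over the 21 pairs it ran from 2.10 (Mi2 with IKAROS) to 46.1 (AIOLOS with IKAROS). It was 10.1 for OCT2 with MTA2, 9.69 for OCT2 with HDAC2, 8.46 for MTA2 with AIOLOS and 7.44 for MTA2 with IKAROS. Values of this size were thus not particular to pairs of NuRD subunits. Peak centres lay a median of 62 bp apart for HDAC2 with MTA2 and 106 bp apart for Mi2 with MTA2. Where they coincided, the peaks were higher: HDAC2 peaks with MTA2 had 1.39 times the median height of those without (bootstrap interval 1.31 to 1.39), and Mi2 peaks with MTA2 had 1.2 times (1.2 to 1.24).

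The highest MTA2 peak in a region of all 3 subunits lay on chromosome 10 between 1613888 and 1614427, with a height of 1065.8 tags per 10 M in the MTA2 library. In the same region the Mi2 height was 110.2 and the HDAC2 height 180.5, and an OCAB peak of height 12 was present without IKAROS or AIOLOS. Next came chromosome 16, 90098449 to 90099016 (MTA2 height 1059.6, HDAC2 height 297.8), and chromosome 20, 51040477 to 51041027 (MTA2 height 702.3). A region of chromosome 1, 18002156 to 18002624, with an MTA2 height of 589.4, held the 3 subunits and none of the other 4 proteins. IKAROS was present in 8 of the 10 regions with the highest MTA2 peaks and AIOLOS in 4. Their IKAROS heights ranged from 15.0, at chromosome 20, 62446650 to 62447109, beside an MTA2 height of 422.1, up to 2783.8.

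Overlap of the subunits depended on the criteria. Regions with all 3 numbered 1071 at the stricter fold over input, 1510 with peak centres within 100 bp, 1867 at the common p-value limit and 337 with 2000 peaks per list, and Mi2 peaks lay with MTA2 at 21.4% with 2000 peaks per list and at 20.004% with peak centres within 100 bp. Mi2 peaks lay with HDAC2 at 21.05% at the stricter fold, 19.8% at the common p-value limit and 17.6% with peak centres within 100 bp. With the other 5 lists in a logistic model and over all merged regions, the odds ratios were 2.5 and 1.15 for Mi2 with MTA2, 4.95 and 4.32 for HDAC2 with MTA2, and 3.30 and 2.15 for Mi2 with HDAC2.

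The second comparison set IKAROS beside AIOLOS. Both were found in 32931 regions; 85.9% of AIOLOS peaks (85.5 to 86.2) overlapped an IKAROS peak, and 60.7% of IKAROS peaks (60.3 to 61.1) overlapped an AIOLOS peak. Of the 21 pairs, it had the highest share, the highest odds ratio, the shortest distance between peak centres and the closest ranking of heights. Its odds ratio was 46.1 (43.4 to 49.1), its peak centres lay a median of 33 bp apart, and the heights of the pair ranked alike across shared regions (Spearman rho 0.886; regions are not independent replicates). AIOLOS peaks with IKAROS had 1.57 times the median height of those without (1.54 to 1.63).

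Regions that held both factors also held the other proteins more often. MTA2 was present in 57.6% of regions with IKAROS and AIOLOS (57.1 to 58.1), in 15.1% of those with IKAROS alone of the pair (14.6 to 15.6) and in 22.7% of those with AIOLOS alone (21.6 to 23.9). For OCT2 the shares were 17.4% (17.0 to 17.8), 3.27% (3.03 to 3.52) and 3.28% (2.83 to 3.80). The highest IKAROS peaks were shared by NuRD: of the 10 regions named by the rule, all 10 held MTA2 and HDAC2 and 9 held Mi2. On chromosome 4, 7865560 to 7865991, the IKAROS height was 2783.8, the AIOLOS height 2249.1 and the MTA2 height 551.3. The region on chromosome 8 from 28747424 to 28747770 had an IKAROS height of 2590.9 and an AIOLOS height of 3149.2. On chromosome 11, 62608995 to 62609365, heights were 2160.7 for IKAROS, 2170.7 for AIOLOS, 111.1 for OCAB and 178.9 for OCT2. The odds ratio of the pair was 27.2 in the logistic model (25.5 to 29.0), still the highest of the 21, and 208 with 2000 peaks per list. Over all merged regions it was 4.57 and no longer the highest, below OCAB with OCT2 (7.41), OCT2 with HDAC2 (5.997) and OCT2 with MTA2 (5.25).

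**Figure D2:**
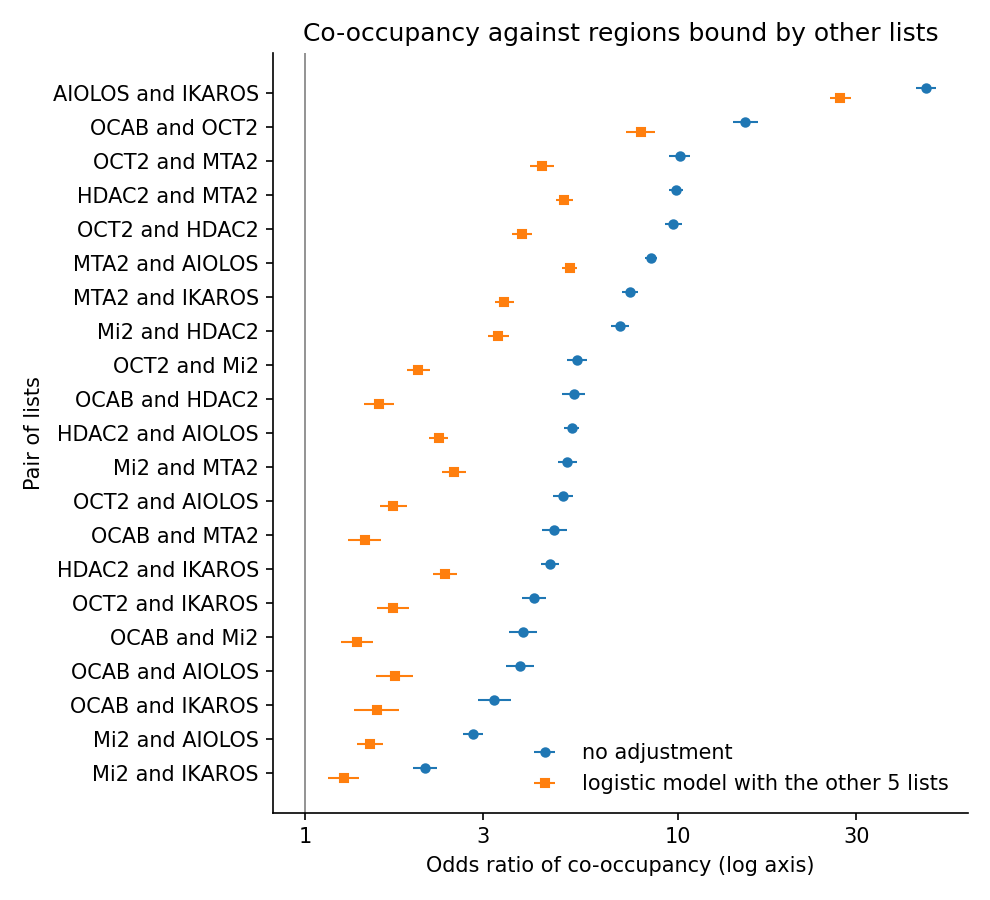
Odds ratio of co-occupancy for each of the 21 pairs of lists on a log axis, over regions with a peak of at least 1 of the other 5 lists (circles) and with those lists as terms of a logistic model (squares); bars are 95% intervals for counting error. IKAROS with AIOLOS stands highest (46.1 and 27.2), then OCAB with OCT2 (15.1 and 7.93).

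The third comparison asked where IKAROS and AIOLOS met NuRD. In the 2903 regions with all 3 subunits, IKAROS was present in 92.5% (91.5 to 93.4), AIOLOS in 88.2% (87.0 to 89.3) and both in 87.1% (85.8 to 88.3). In the 26831 regions with exactly 1 of the subunits, IKAROS was present in 52.5% (51.9 to 53.1) and both factors in 40.3% (39.7 to 40.9). Regions with exactly 2 subunits lay between, with IKAROS in 86.4% (85.7 to 87.1). The 34576 regions with none of the subunits held IKAROS in 83.0% (82.6 to 83.3), but these enter the set only through 1 of the other 4 lists, of which IKAROS is the longest. Over regions that hold AIOLOS, OCAB or OCT2, a background added after the data were seen, IKAROS was present in 67.7% with no subunit (67.0 to 68.4), 87.1% with 1 (86.5 to 87.7), 95.2% with 2 (94.8 to 95.7) and 95.5% with 3 (94.7 to 96.2).

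Shares differed between subunits, in classes that regions can enter through the subunits alone. IKAROS was found in 67.4% of regions with MTA2 alone among the subunits (66.7 to 68.1), in 42.7% of those with HDAC2 alone (41.3 to 44.1) and in 14.9% of those with Mi2 alone (13.9 to 15.8). No other protein was found in 4233 of these 16680 MTA2 regions, 2473 of the 4803 HDAC2 regions and 4402 of the 5348 Mi2 regions. Such regions lower the IKAROS share, most of all for Mi2. The shares were not recomputed without them, so much of the contrast between subunits can come from how regions enter, and its size is not settled here. Regions with Mi2 and HDAC2 but no MTA2 had IKAROS in 40.8% (37.1 to 44.6), against 90.9% of those with MTA2 and HDAC2 but no Mi2 (90.2 to 91.5). Of these, 335 of 654 and 453 of 7762 held no other protein. IKAROS peaks with MTA2 had 2.54 times the median height of IKAROS peaks without it (2.51 to 2.59), with medians of 38.1 and 15.0, and AIOLOS peaks with MTA2 had 1.86 times (1.82 to 1.93). The reverse ratio, MTA2 height with against without IKAROS, was 1.31 (1.31 to 1.35).

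Across shared regions, MTA2 height ranked with IKAROS height (rho 0.691) and AIOLOS height (rho 0.677). Of the 10 regions with the highest MTA2 peaks among those with all 3 subunits and IKAROS or AIOLOS, 6 held AIOLOS. On chromosome 4, 185886161 to 185886745, the MTA2 height was 641.0 with an IKAROS height of 2492.1 and an AIOLOS height of 2916.4. A region on chromosome 14, 106033533 to 106034045, had an MTA2 height of 390.6 and heights of 19.7 for IKAROS and 16.8 for AIOLOS. With 2000 peaks per list, IKAROS was present in 67.7% of regions with all 3 subunits and 16.7% of regions with 1. The odds ratio of Mi2 with IKAROS was 2.10 (1.95 to 2.25) and 1.27 in the logistic model (1.16 to 1.4), but 0.864 in strata by the number of other lists and 0.275 over all merged regions, so its direction depended on the background.

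**Figure D3:**
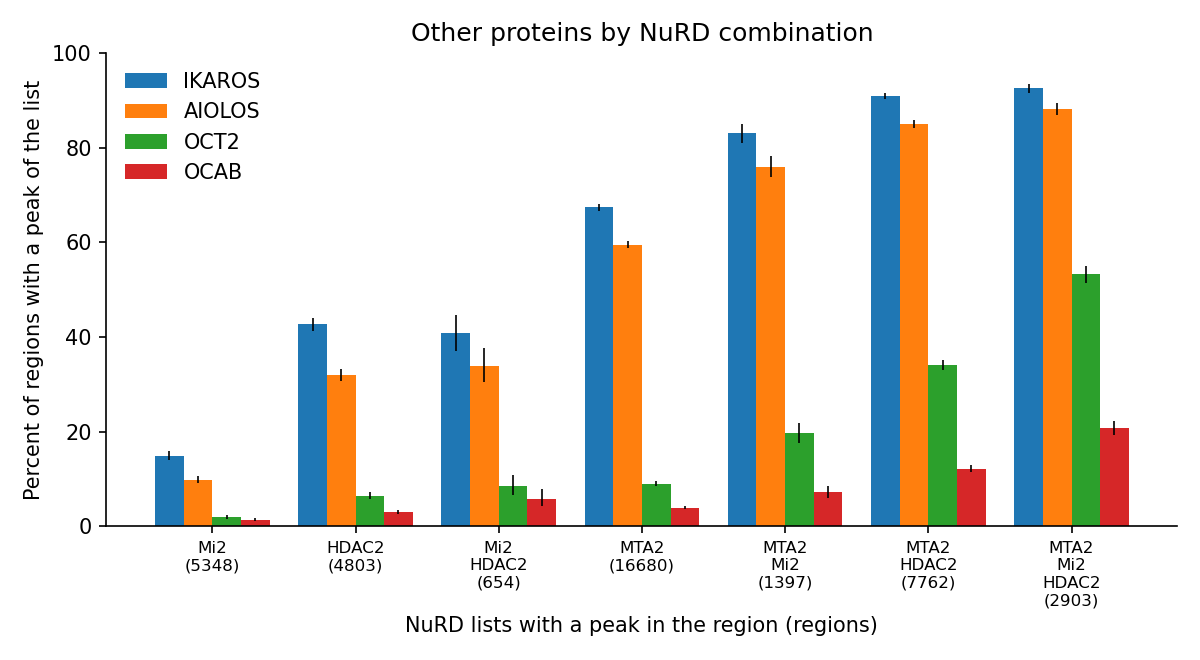
Percent of regions with an IKAROS, AIOLOS, OCT2 or OCAB peak, by the combination of NuRD subunits in the region (number of regions in brackets); bars are shares and error bars are Wilson 95% intervals for counting error. Among the classes drawn, IKAROS was lowest at Mi2 alone (14.9%) and highest at all 3 subunits (92.5%), as was OCT2 (1.93% and 53.3%). Regions can enter these classes through a subunit alone. Regions with none of the subunits, not drawn, held IKAROS in 83.0% and OCT2 in 4.88%. Over regions with AIOLOS, OCAB or OCT2, IKAROS was in 87.1% with 1 subunit and 95.5% with 3.

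The fourth comparison set OCAB beside OCT2, the factor through which it can be brought to octamer sites. They shared 1874 regions. Of OCAB peaks, 41.2% (39.8 to 42.7) overlapped an OCT2 peak, and 22.5% of OCT2 peaks (21.6 to 23.4) overlapped an OCAB peak, against 0.168% of OCAB peaks under random placement. The odds ratio of 15.1 (14.0 to 16.3) was exceeded among the 21 pairs by that of IKAROS with AIOLOS alone, and peak centres lay a median of 43 bp apart. OCT2 peaks with OCAB had 1.41 times the median height of those without (1.32 to 1.46). Among OCAB peaks, OCT2 was present at 26.3% of the lowest 25% by height (23.8 to 29.0) and at 59.7% of the highest 25% (56.8 to 62.6).

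The highest OCAB peak with OCT2 lay on chromosome 19, 44123888 to 44124298, with an OCAB height of 355.0 and an OCT2 height of 62.2. The next lay on chromosome 17, 62009431 to 62009914, where OCAB height was 337.3 and MTA2 height 49.5, and on chromosome 1, 233275907 to 233276229, with an OCAB height of 261.0. Of the 10 regions so named, 9 held MTA2, 9 held IKAROS and 8 held AIOLOS, while 1 held Mi2. The exception to MTA2 was on chromosome 6, 20401859 to 20402155, where OCAB (height 241.6) and OCT2 (height 15.3) were the only proteins found. With 2000 peaks per list, 26.3% of OCAB peaks overlapped OCT2, and the odds ratio was 7.93 in the logistic model (7.25 to 8.68) and 7.41 over all merged regions.

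The last comparison, the one named in the series title, asked how often OCAB and OCT2 lay with MTA2. MTA2 was found at 48.9% of OCAB peaks (47.4 to 50.3) and at 70.8% of OCT2 peaks (69.8 to 71.8), where random placement gave 0.580% and 0.591%. Among OCAB regions, the presence of OCT2 went with MTA2: MTA2 was found in 80.8% of the 1874 regions with OCAB and OCT2 (79.0 to 82.6) and in 30.4% of the 2564 regions with OCAB and no OCT2 (28.6 to 32.2). The difference was 50.5 percentage points (47.9 to 52.9). In regions with none of IKAROS, AIOLOS and HDAC2, MTA2 was rarer in both groups. It was found in 13.4% of 142 regions with OCAB and OCT2 (8.74 to 19.95) and 4.74% of 1307 with OCAB and no OCT2 (3.72 to 6.03). The difference there was 8.64 points (3.82 to 15.3), from lower shares and 19 MTA2 regions with OCT2, so the 2 differences in points are not directly comparable. In the 6253 regions with OCT2 and no OCAB, MTA2 was found in 71.2% (70.1 to 72.4), 9.60 points below the regions with both (7.45 to 11.7). The 63432 regions with neither protein held MTA2 in 34.7% (34.3 to 35.0), but these enter the set only through the other 5 lists, MTA2 among them. Over regions that hold Mi2, HDAC2, IKAROS or AIOLOS, a background added after the data were seen, MTA2 was found in 86.1% with OCAB and OCT2 (84.4 to 87.7), 55.7% with OCAB alone of the pair (52.9 to 58.3), 81.4% with OCT2 alone (80.3 to 82.4) and 30.001% with neither (29.6 to 30.4), and the difference of the first 2 was 30.5 points (27.3 to 33.6).

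The other proteins were also found more often where OCAB lay with OCT2. HDAC2 was present in 67.0% of regions with OCAB and OCT2 (64.9 to 69.1), 18.3% of those with OCAB alone of the pair (16.9 to 19.9) and 52.7% of those with OCT2 alone (51.5 to 54.0). For Mi2 the shares were 31.2% (29.1 to 33.3), 9.09% (8.04 to 10.3) and 22.3% (21.3 to 23.4), and for IKAROS 88.8% (87.3 to 90.1), 44.1% (42.2 to 46.0) and 76.0% (74.9 to 77.0). Regions with neither held HDAC2 in 17.5%, Mi2 in 12.8% and IKAROS in 73.1%, again entering only through the other 5 lists. Over regions that hold at least 1 of the other 4 lists apart from OCAB and OCT2, a background added after the data were seen, OCAB regions with OCT2 exceeded those without by 37.8 points for HDAC2 (34.5 to 41.1, against 48.7 over all), 18.1 for Mi2 (15.2 to 21.02, against 22.1) and 13.6 for IKAROS (11.1 to 16.1, against 44.7). On this background OCAB regions without OCT2 held more than regions with neither, with 33.4% against 14.1% for HDAC2, 14.9% against 6.24% for Mi2 and 81.0% against 63.8% for IKAROS. OCT2 peaks with MTA2 had 1.33 times the median height of those without (1.32 to 1.4). For OCAB peaks with and without MTA2 the ratio was 1.04 (0.963 to 1.07), not distinguishable from no difference, and MTA2 peaks with OCAB had 1.72 times the median height of MTA2 peaks without (1.63 to 1.8).

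OCAB and MTA2 shared 2294 regions, of which 93.1% held IKAROS (92.0 to 94.0), 90.0% AIOLOS (88.7 to 91.1), 67.3% HDAC2 (65.4 to 69.2), 66.0% OCT2 (64.1 to 68.0) and 30.6% Mi2 (28.8 to 32.6). Of the 10 regions with the highest OCAB peaks among them, 8 held OCT2 and 9 held AIOLOS. The highest without OCT2 lay on chromosome 12, 31478781 to 31479431, with an OCAB height of 335.6 and an MTA2 height of 152.8. A region on chromosome 19, 41282874 to 41283419, held all 7 proteins, with heights of 219.9 for OCAB, 145.4 for IKAROS and 33.3 for MTA2.

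Over regions bound by other proteins, the odds ratio was 10.1 for OCT2 with MTA2 (9.48 to 10.7) and 4.66 for OCAB with MTA2 (4.31 to 5.04). With the other 5 lists in a logistic model these were 4.32 (4.01 to 4.66) and 1.45 (1.30 to 1.60), and in regions without IKAROS, AIOLOS and HDAC2, MTA2 was found at 18.4% of OCT2 sites and 5.59% of OCAB sites. With 2000 peaks per list the overlaps with MTA2 were 36.4% and 16.1%.

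**Figure D4:**
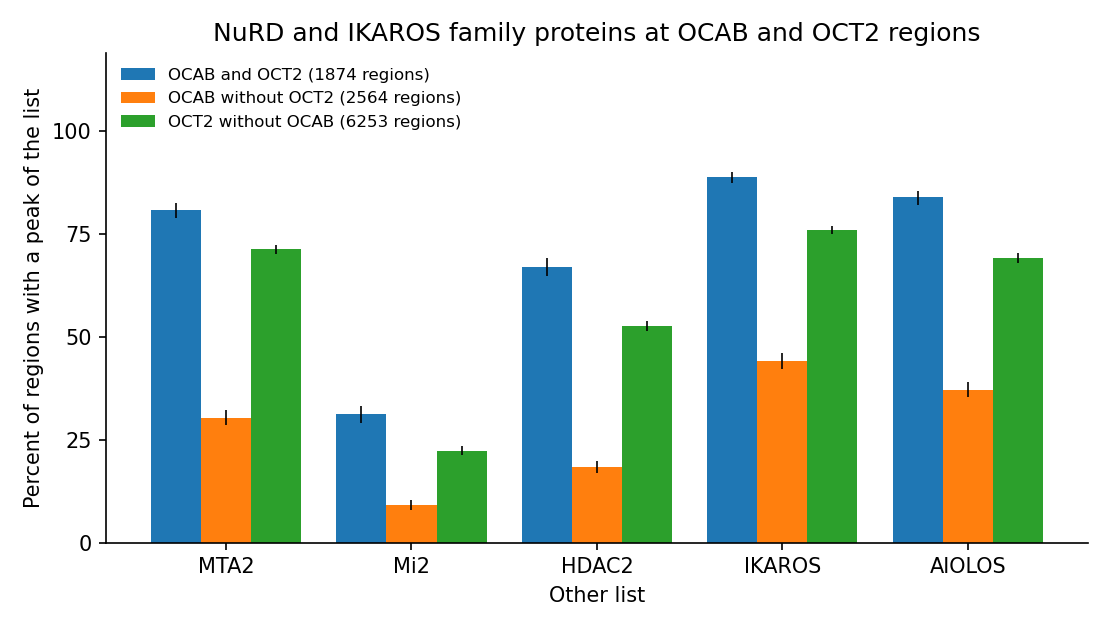
Percent of regions with a peak of MTA2, Mi2, HDAC2, IKAROS or AIOLOS among regions with OCAB and OCT2, with OCAB but no OCT2, and with OCT2 but no OCAB; bars are shares and error bars are Wilson 95% intervals for counting error. For MTA2 the 3 shares were 80.8%, 30.4% and 71.2%.

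Peak height was also followed with the number of proteins in a region. Median IKAROS height was 11.5 tags per 10 M where IKAROS was alone (11.1 to 11.5) and 101.8 where all 7 proteins were found (96.9 to 110). AIOLOS went from 14.9 (14.3 to 14.9) to 81.9 (75.6 to 88.4), MTA2 from 10.9 (10.9 to 11.4) to 40.7 (38.1 to 42.5), HDAC2 from 11 to 24.7 (22.9 to 25.7), OCT2 from 10.4 to 22.4 (21.3 to 25.1) and Mi2 from 13 to 19.5 (18.9 to 20.5). OCAB went from 13.7 (13.1 to 14.2) where alone to 16.5 in regions of 2 lists (16 to 17.7) and was again 16.5 in regions of all 7 (16 to 17.7).

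**Figure D5:**
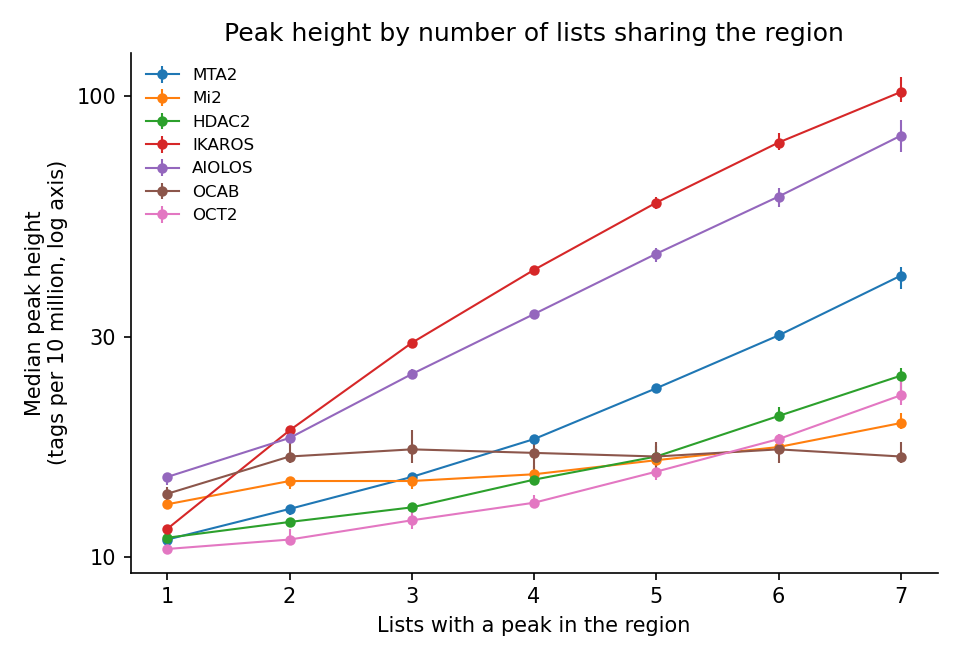
Median peak height in tags per 10 M (log axis) against the number of lists with a peak in the region, for each of the 7 lists; error bars are 95% bootstrap intervals over peaks. IKAROS rises from 11.5 to 101.8, whereas OCAB stays at 16.5 in regions of 2 lists and of all 7; heights are to be read within a list.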

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

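The lists were searched, after the data were seen, for peaks on sequence outside the assembled chromosomes, which no comparison above names. In 4 lists the highest peak of all lay there, above every peak on an assembled chromosome. The highest IKAROS peak had a height of 4438.5 tags per 10 M and 393-fold over input, and the highest AIOLOS peak a height of 4889.7 and 434-fold. Both lay on 1 unplaced chromosome 17 sequence, within a few bases of each other, from 87280 to 87552 for IKAROS and from 87283 to 87539 for AIOLOS. The highest peaks on assembled chromosomes were 2783.8 for IKAROS and 3149.2 for AIOLOS. The same sequence held the highest Mi2 and HDAC2 peaks outside the chromosomes, with heights of 103.7 and 198.8.

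The highest MTA2 peak, with a height of 1106.5, and the highest OCT2 peak, with a height of 1212.2, lay on another unplaced sequence, at different positions. Their fold over input was lower, at 12.1 for MTA2 and 5.87 for OCT2, and the highest peaks on assembled chromosomes were 1065.8 and 570.1. OCAB had 1 peak outside the chromosomes, with a height of 33.0. In all, 39 IKAROS peaks, 27 AIOLOS peaks, 24 HDAC2 peaks, 16 MTA2 peaks, 6 Mi2 peaks and 2 OCT2 peaks lay on such sequence.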

How the results depend on the processing

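The alternatives on p-value limit, HDAC2, strata, logistic model, regions without IKAROS, AIOLOS and HDAC2, and regions that enter through lists outside a comparison were added after the data were seen. Of 191 odds ratios under alternatives, 187 stayed above 1 with their interval, and 17 of 18 height ratios did; that of OCAB with MTA2 had an interval that included 1, as in the main setting. Of 35 counts of peaks or regions, 21 stayed within 1.5 times the main count. Of 416 values with an interval, 144 stayed inside the interval of the main value, 268 moved outside it and 4 changed direction: Mi2 with IKAROS (0.275) and with AIOLOS (0.658) and OCAB with IKAROS (0.617) over all merged regions, where a region can enter through the pair itself, and Mi2 with IKAROS (0.864) in strata by the number of other lists. Of 171 moved values for pairs and medians not counted as answering a comparison, some of them given above, 138 were lower than the main value and 33 higher. Chromosomes 1 to 22 alone moved no value that answers a comparison. Except where the construction is named, the cause was not tested. No paired analysis was possible because each antibody had 1 library. Promoter share, promoter definition, distal regions only, gene lists and motif share were not run, since they need an annotation or sequence of the build used. The HDAC2 library was the shallowest at 10.9 M tags. How far depth limits each list was not tested, and an absent peak is not absent binding.

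Where the fold over input was at least 2 times the lowest, Mi2 kept 6386 peaks and HDAC2 7104. Shares with MTA2 were 30.1% for Mi2, 38% for OCAB and 64.8% for OCT2, with odds ratios of 4.49, 3.64 and 9.40. AIOLOS lay with IKAROS at 82.4% and OCAB with OCT2 at 31.3% (odds ratio 13.3). All 3 NuRD subunits met in 1071 regions, with IKAROS in 86.5%, AIOLOS in 81.1% and both in 79.7%, and IKAROS was in 55.0% of regions with 1 subunit.

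With the 2000 highest peaks of each list, all lists held 2000 peaks by construction and shares fell with list length. Shares with MTA2 were 21.4% for Mi2, 49.95% for HDAC2, 16.1% for OCAB and 36.4% for OCT2, with odds ratios of 4.57, 14.8, 2.82 and 6.12. AIOLOS lay with IKAROS at 80.2% (208) and OCAB with OCT2 at 26.3% (11.9). There were 337 regions with 3 subunits, with IKAROS in 67.7%, AIOLOS in 64.7% and both in 62.9%, against IKAROS in 16.7% with 1 subunit. MTA2 share of OCAB regions with OCT2 exceeded that without by 44.3 points.

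Requiring overlap by 50 percent of the shorter peak gave shares with MTA2 of 29.4% for Mi2, 54.4% for HDAC2, 39.8% for OCAB and 63.3% for OCT2. AIOLOS lay with IKAROS at 81.4% (odds ratio 51.3) and OCAB with OCT2 at 38.2% (18.3). Regions with 3 subunits held IKAROS in 90.6%, AIOLOS in 85.9% and both in 84.5%, and those with 1 held IKAROS in 45.3%. Height ratios were 1.26 for MTA2 with IKAROS, 1.16 for Mi2 with MTA2, 1.12 for Mi2, 1.22 for HDAC2 and 1.22 for OCT2 with IKAROS.

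Peak centres within 100 bp gave shares with MTA2 of 20.004% for Mi2 (odds ratio 4.48), 44.6% for HDAC2, 34.3% for OCAB (5.12) and 57.4% for OCT2. AIOLOS lay with IKAROS at 76.9% (51.8) and OCAB with OCT2 at 34.6% (20.6). There were 1510 regions with 3 subunits, with IKAROS in 88.3%, AIOLOS in 83.6% and both in 81.9%, and IKAROS in 39.6% with 1 subunit.

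With a p-value limit of 1e-10 for every list, HDAC2 kept 6674 peaks, 76.6% of them with MTA2 (odds ratio 13.8). Mi2 with MTA2 had an odds ratio of 5.46, and OCT2 lay with MTA2 at 72.2%, AIOLOS with IKAROS at 85.2% and OCAB with OCT2 at 38.9%. There were 1867 regions with 3 subunits, and IKAROS was in 58.4% of regions with 1. Leaving HDAC2 out, regions with MTA2 and Mi2 held IKAROS in 89.5%, AIOLOS in 84.3% and both in 82.2%.

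Over all merged regions, in strata by the number of other lists and in the logistic model, the odds ratio was 1.15, 2.53 and 2.5 for Mi2 with MTA2. It was 4.32, 4.82 and 4.95 for HDAC2 with MTA2, 1.75, 1.45 and 1.45 for OCAB with MTA2, and 5.25, 3.71 and 4.32 for OCT2 with MTA2. For AIOLOS with IKAROS it was 4.57, 34.4 and 27.2, and for OCAB with OCT2 7.41, 7.14 and 7.93. In regions without IKAROS, AIOLOS and HDAC2, MTA2 was found at 5.59% of OCAB regions and 18.4% of OCT2 regions. The odds ratio with MTA2 was 2.34 for OCAB, over those of these regions that also held Mi2 or OCT2. For OCT2 it was 6.93, over those that also held Mi2 or OCAB. Over all regions without IKAROS, AIOLOS and HDAC2, the MTA2 share of OCAB regions with OCT2 (13.4%) exceeded that of those without (4.74%) by 8.64 points (3.82 to 15.3). Over regions with Mi2, HDAC2, IKAROS or AIOLOS that difference was 30.5 points. Over regions with AIOLOS, OCAB or OCT2, IKAROS was in 87.1% of regions with 1 subunit and 95.5% of those with 3; regions that held a subunit and no such protein were left out by construction.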

Other observations

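All tests in this part bear on patterns that had already been seen. For the test of OCAB peaks by height and the draws of OCAB peaks over windows, the expected outcomes were written before the test. The other tests were chosen after the results they bear on had been seen. Of the 100 highest MTA2 peaks on chromosomes 1 to 22 and X, 34.0% (25.5 to 43.7) lay within 2 Mb of the first or last peak of the chromosome, where the shares were 18.0% (11.7 to 26.7) for HDAC2, 15.0% (9.31 to 23.3) for Mi2, 11% (6.25 to 18.6) for OCT2, 10.0% (5.52 to 17.4) for IKAROS, 9% (4.81 to 16.2) for AIOLOS and 5% (2.15 to 11.2) for OCAB. Over whole lists the shares lay closer together, from 5.43% for Mi2 to 7.70% for MTA2, and these ends made up 3.13% of the covered length. Chromosome X held 2.41% of IKAROS peaks, 2.03% of AIOLOS, 1.84% of MTA2, 1.49% of OCT2, 1.35% of OCAB, 1.15% of HDAC2 and 1.01% of Mi2 peaks.

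OCAB had 1209 peaks at which none of the other 6 proteins was found. The highest of them lay on chromosome 16, 89008433 to 89008699, with a height of 220.5, and on chromosome 12, 99038936 to 99039202, with a height of 182.3 and 387-fold over input. These were chosen by height after the values were seen.

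OCAB regions with OCT2 held MTA2 more often than OCAB regions without it, by 50.5 points over all regions, 30.5 points over regions with Mi2, HDAC2, IKAROS or AIOLOS, and 8.64 points over regions with none of IKAROS, AIOLOS and HDAC2. MTA2 was rare in the last set, at 13.4% with OCT2 and 4.74% without, so its difference in points is not directly comparable. Low OCAB peaks in the regions without OCT2 do not account for the whole pattern: in the highest 25% of OCAB peaks the difference in MTA2 share was still 40.4 points (34.7 to 45.6). In the lower classes of 25% it was larger, at 55.8, 56.0 and 57.3 points from the lowest up. Among OCAB peaks with OCT2, MTA2 was at 69.7% in the highest class and at 85.3% to 89.9% in the lower ones. A general crowding of proteins where OCT2 sits may account for much of the pattern, and whether it accounts for all was not decided. Within OCAB regions the odds ratio of OCT2 with MTA2 was 9.67 (8.39 to 11.2), and 2.47 (2.03 to 2.99) once compared within the 16 patterns of IKAROS, AIOLOS, Mi2 and HDAC2. These patterns record presence alone, so crowding can still vary in strength within each. From the lowest to the highest 25% of IKAROS peaks, MTA2 rose from 11.7% to 81.0% and OCT2 from 2.39% to 31.0%. The remaining odds ratio thus cannot separate a tie of OCT2 with MTA2 from crowding. Open chromatin and the sequence under the peaks were not tested here, and a link of MTA2 to OCAB through OCT2 remains a hypothesis.

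Height rose with the number of proteins in a region. Input signal was argued against for IKAROS, AIOLOS, MTA2 and HDAC2, where the rise in height from 1 list to 7 exceeded the rise in input tags by at least 1.60 times (1.47 to 1.69, HDAC2) and by up to 5.99 times (5.61 to 6.56, IKAROS). In Mi2 the rise was no larger than that of input, with a ratio of 0.873 (0.830 to 0.925), so input signal could account for it there; from 2 to 7 lists both its height (1.34 times, 1.29 to 1.43) and its input tags (1.47 times, 1.39 to 1.56) rose. For OCAB the rise from 1 to 7 lists was also no larger than that of input, with a ratio of 0.816 (0.760 to 0.877), but input as the whole cause was argued against by the step from 2 to 7 lists, where OCAB height did not rise (ratio 1, 0.907 to 1.07) while its input tags rose 1.33 times (1.22 to 1.44). OCT2 stays open, with height over input of 1.22 (1.12 to 1.36) from 1 to 7 lists, and of 1.74 (1.27 to 2.51) from 2 to 7 lists, where the input ratio was poorly determined (0.819 to 1.63). A signal common to every antibody was argued against for OCAB, whose height ranked with that of other lists with a rho of at most 0.277. Between the other 6 lists rho ran from 0.413 to 0.886, so a common signal stays open for them, and sites shared by these proteins would give the same. No biological explanation was tested.

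OCAB peaks were dense in a few windows of 1 Mb. Of the 11 windows with at least 10 OCAB peaks, the densest lay on chromosome 2 from 89 to 90 Mb (13 peaks, 7.62 times the density of regions of the other lists, 3.63 to 15.2), chromosome 22 from 22 to 23 Mb (23 peaks, 4.78 times, 2.87 to 7.69) and chromosome 14 from 107 to 108 Mb (11 peaks, 4.52 times, 2.09 to 8.97). Chance among windows was argued against for the densest, since the highest of 1000 random draws reached 6.32 and 3 windows passed the 95th percentile of 4.11. A rise in input or copy number as large as the rise in density was argued against for these 3 windows pooled. Their 47 OCAB peaks had mean input tags 1.04 times (0.861 to 1.27) those of all OCAB peaks, which leaves a smaller rise open. By window the means were 2.55 on chromosome 2, 3.16 on chromosome 22 and 3.25 on chromosome 14, against 2.88. For chromosome 14 alone higher input or copy number stays open, since mean input tags there were raised in every list. Among them were IKAROS (5.07 against 3.76), Mi2 (5.10 against 3.40), HDAC2 (3.09 against 2.29) and AIOLOS (3.78 against 2.93). Higher input or copy number also stays open in the next 2 windows. These lay on chromosome 1 from 167 to 168 Mb (3.79 times the density) and chromosome 22 from 23 to 24 Mb (2.68 times). Mean input tags of OCAB peaks there were 4.56 and 4.28 against 2.88 for all OCAB peaks. In the chromosome 1 window the input tags of MTA2 peaks (7.10 against 3.69) and IKAROS peaks (7.26 against 3.76) were raised too, while the density of peaks stood at 0.945 times for MTA2, 0.908 for IKAROS, 1.01 for AIOLOS, 1.002 for OCT2, 1.23 for HDAC2 and 1.8 for Mi2. Raised input thus did not go with denser peaks in most lists there. On chromosome 22 from 23 to 24 Mb, input was raised in OCT2 (3.59 against 3.20), MTA2 (4.19 against 3.69) and HDAC2 (2.65 against 2.29). Their densities stood at 1.77, 1.28 and 1.27 times. IKAROS and AIOLOS, with input raised as well, stood at 1.02, and Mi2, with input not raised, at 0.628. Each list is set against regions of the others, which share that input, and whether OCAB peak calls respond to input more strongly was not tested. OCT2, on which the windows were not chosen, stood at 1.64, 1.74 and 2.004 times in the 3 densest, from 6, 16 and 10 peaks, and 3, 12 and 4 of the OCAB peaks there held OCT2, so the OCT2 and OCAB counts are not independent. On chromosome 2 the other 5 lists stood below 1, from 0.261 (HDAC2) to 0.986 (IKAROS). In the densest windows on chromosomes 22 and 14 HDAC2 (1.63 and 1.45) and MTA2 (1.42 and 1.45) were raised as well, and IKAROS stood at 0.878 and 0.706. Chromosomes 2, 22 and 14 carry the immunoglobulin kappa, lambda and heavy chain genes, which octamer factors regulate, but gene positions on this build were not used here and near-identical gene copies were not tested, so dense OCAB binding at those genes is a hypothesis.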
